A study of Arabidopsis thaliana with 40 samples.

How the data were processed

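Messenger RNA was sequenced from the root and, separately, from the shoot (the aerial part) of Arabidopsis thaliana seedlings of 5 genotypes, with 4 replicates of each, which gives 40 libraries in 10 groups. The genotypes were the Col-0 wild type (wt), bz1728, nobiro6, nbr6-t1 and taf12-t1. The line bz1728 is a double T-DNA mutant of BZIP17 and BZIP28, membrane-anchored transcription factors of the unfolded protein response. The line nobiro6 carries a suppressor mutation in the bz1728 background, nbr6-t1 is a T-DNA line of TAF12B, and taf12-t1 is a T-DNA line of its paralog TAF12. TAF12B and TAF12 are subunits of the general transcription factor TFIID. Per the labels, seeds were kept at 4 °C for 3 d, and plants were grown on agar plates at 22 °C, 65% relative humidity and 16 h of light. The labels give the age at harvest both as 12 d and as 13 days after sowing.

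The authors trimmed reads with Trimmomatic 0.39 and estimated transcript abundance with kallisto 0.44.0. The deposited expected counts are kallisto estimates of reads per transcript, not scaled for library depth, and the deposited TPM values are scaled by effective length and library total and summed to 1000000 in each library. Each deposited table listed 27655 transcripts, 1 per locus. Between 97.7 and 98.5% of the expected counts in a library were whole numbers within 1e-06. The genome build and annotation release behind the tables are not given in the sources used here, so no coordinates are given. Gene symbols came from a reference annotation in which 27445 of the 27655 loci were found, 10378 of them with a symbol. The same annotation gave the neighbours of a locus and the 31-mers of its transcripts.

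Expected counts were rounded and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM factors, filterByExpr at its defaults (a count of 10, a total of 15) and robust quasi-likelihood F-tests on genotype means. The 20 libraries of a tissue were fitted together, and all 40 for the root minus shoot differences. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are counts scaled with TMM factors to a library total of 1000000 (CPM), given as mean ± SD over 4 libraries. A log2 fold change is given with an approximate standard error, the absolute change divided by the square root of F. Where a group holds few counts this error can be too small, and it is not read as an interval there. The tests are two-sided. Where all libraries of a group held 0 counts, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only.

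The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The 17 lists were ER folding; ERAD, translocation and ER export; stress-type UPR (unfolded protein response) markers; TFIID and SAGA subunits; cell cycle; root hair; endodermis and suberin; salicylic acid and immunity; jasmonate; ABA, cold and drought; cytosolic heat shock; photosynthesis; root-abundant; iron deficiency; phosphate starvation; ethylene; and auxin response. They were written with 275 members. Of these, 4 were dropped because the annotation pairs their locus with another symbol, and 6 were kept by locus code. Named genes are the 4 mutated genes and, for each comparison, members of the lists with the smallest adjusted p (up to 4 per list, and all members of the ER folding and stress-type UPR lists). They also include the genes with the largest fold changes (8 each way in root, 5 in shoot) among those called, with a mean log2 CPM of at least 1, no overlap between groups and a symbol. For the interactions, they are the 4 genes each way with the smallest adjusted p that have a symbol, except 1 that is not reported here. Each list was tested with camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Members were also counted with p adjusted over the list alone.

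The comparisons were bz1728, nbr6-t1 and taf12-t1 against wt, nobiro6 against bz1728 and against wt, and taf12-t1 against nbr6-t1, in each tissue. Interactions tested whether a difference was unequal between root and shoot, and whether nobiro6 against bz1728 was unequal to nbr6-t1 against wt. Overlaps of called genes were set against the number expected for independent lists. Because comparisons that share a group also share its error, each such overlap was also counted with the shared group's libraries split between the comparisons (6 splits), and the relation of the log2 fold changes across genes was also computed in 20 simulations without any genotype difference. Tested on data simulated at the root depth and spread, the method recovered 66.1% of the genes changed 1.5-fold between bz1728 and wt, 88% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls. At the shoot depth and spread the shares were 35.3%, 75.3% and 96.6%, with 16 false calls. These 16 stood beside 24, 55 and 57 recovered genes in shoot, and the 8 in root beside 41, 66 and 63. In root 62, 75 and 63 of 18330 simulated genes were changed, and in shoot 68, 73 and 59 of 17026. The real pairwise comparisons called 7.5 to 47.2% of tested genes, so the simulated shares and false calls are not read as rates for them.

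Alternatives were RLE and upper-quartile factors, no low-count filter, the replicate number as a block, the compared groups alone, DESeq2 1.42.0, limma-trend on log2(TPM + 1), leaving out each replicate, a threshold of 0.01 for the overlaps, and fry or an estimated correlation for the lists. Thinning every library to 2.66 M counts was added after the data had been seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out.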

Results

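Transcript abundance was measured in root and shoot libraries of 5 genotypes, 4 libraries per genotype and tissue. Library totals ran from 2.66 to 12.9 M counts, with a median of 4.46 M in root and 5.08 M in shoot. Shoot wt was sequenced deepest, with 7.58 to 12.9 M counts, and the other groups held 2.66 to 8.2 M. A single count stood for 0.375 CPM in the smallest root library and 0.292 CPM in the smallest shoot library. The biological coefficient of variation was 0.0811 in root and 0.119 in shoot. In root 18745 genes were tested, and in shoot 17382. Unless stated otherwise, levels are mean CPM ± SD and errors of log2 fold changes are the approximate standard errors. There were n = 4 libraries per group, and adjusted p values are from edgeR for genes and camera for lists.

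The mutated genes themselves were read first. BZIP28 (AT3G10800) had 0 counts in all 8 bz1728 libraries, against 71.7 ± 3.77 CPM in wt root and 34.5 ± 5.44 in wt shoot. This was at least 542-fold lower in root and at least 229-fold lower in shoot. BZIP17 (AT2G40950) stood at 5.55 ± 1.15 CPM in bz1728 root against 51.7 ± 2.69 in wt, and at 2.8 ± 0.762 against 29 ± 2.72 in shoot. In taf12-t1 it was higher than in wt, at 68.4 ± 5.58 CPM in root and 42.1 ± 2.18 in shoot. In nbr6-t1 it stood at 56 ± 2.72 and 31.2 ± 3.21 CPM. In the libraries labelled nobiro6, BZIP17 stood at 4.85 ± 1.48 CPM in root and 2.44 ± 1.06 in shoot, whereas BZIP28 stood at 13.9 ± 3.32 CPM in root and 26.9 ± 3.26 in shoot. BZIP28 was therefore at least 108-fold higher than in bz1728 in root and at least 182-fold higher in shoot, and a difference between nobiro6 and bz1728 includes this gene. The next gene AT3G10810, read after its values were seen, stood at 37.2 ± 3.7 CPM in wt root, 0 in bz1728 and 46.6 ± 4.76 in nobiro6, and AT3G10815 at 7.74 ± 1.47, 0 and 9.01 ± 1.22. Each comparison with bz1728 therefore also includes these genes.

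TAF12B (AT1G17440) fell in nobiro6 against bz1728 by 0.73 ± 0.1 on the log2 scale in root and by 1.24 ± 0.12 in shoot. In the T-DNA line nbr6-t1, TAF12B stood at 14.2 ± 2.39 CPM in shoot against 48.7 ± 5.07 in wt. In root it stood at 58.8 ± 4.8 CPM against 53.1 ± 5.32 (log2 fold change 0.15 ± 0.08, adjusted p 0.2, not called). The root and shoot changes differed by 1.99 ± 0.14 (edgeR adjusted p 2.4e-13). TAF12 (AT3G10070) in taf12-t1 was higher than wt in root (20.6 ± 3.89 against 10.2 ± 0.512 CPM) and lower in shoot (6.97 ± 1.55 against 9.95 ± 0.975), and these changes differed by 1.55 ± 0.23 (edgeR adjusted p 2.7e-06). Of the TAF12 31-mers 5.43% occur in AT3G10060 as well, so reads from that gene are not excluded for TAF12, and whether the root libraries labelled taf12-t1 carry the insertion was not tested.

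**Figure D1:**
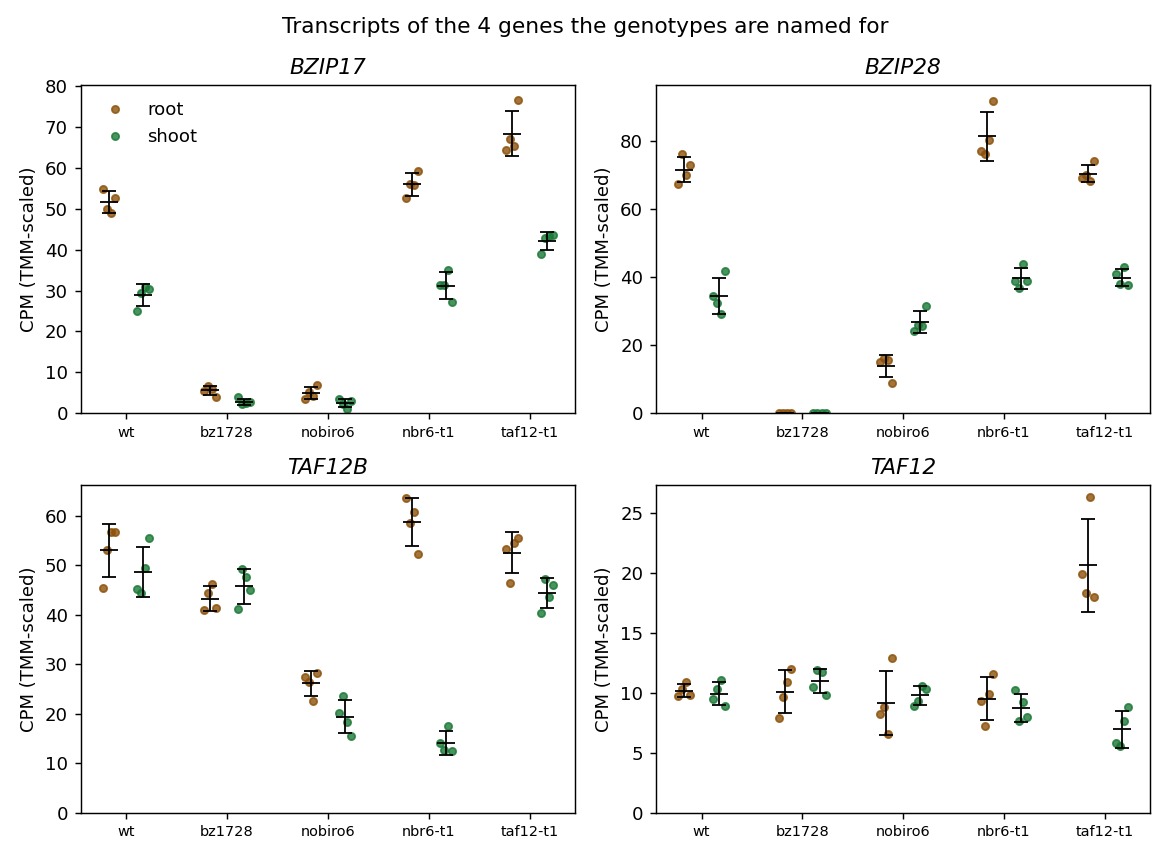
Levels of BZIP17, BZIP28, TAF12B and TAF12 in CPM (vertical axis) by genotype in root and shoot (horizontal axis), with a point per library and the mean ± SD of 4 libraries. BZIP28 lies at 0 in bz1728 and at 13.9 (root) and 26.9 (shoot) in nobiro6, and TAF12B in nbr6-t1 lies at 14.2 in shoot and 58.8 in root.

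In root, bz1728 was compared with wt. Stress-type markers of the unfolded protein response were strongly raised. SEC31A (AT1G18830), which encodes a coat protein of vesicles leaving the ER, stood at 790 ± 92.5 CPM against 0.279 ± 0.274 in wt (log2 fold change 11.32 ± 0.23). BIP3 (AT1G09080), a stress-induced ER chaperone, was at least 149-fold higher (16.9 ± 5.19 CPM against 0). The transcription factor genes NAC103 and BZIP60 rose by 5.81 ± 0.27 and 1.92 ± 0.07. Of the 9 stress-type markers 8 rose and TIN1 (-1.18 ± 0.21) fell, with the same counts adjusted over the list alone (camera adjusted p 9.1e-31; 1.2e-05 with an estimated correlation).

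The ER folding list went both ways in bz1728 root. ERDJ3A, ERO1, PDIL1-2 and PDIL2-3 rose, by 3.26 ± 0.13 for ERDJ3A and 2.3 ± 0.08 for PDIL1-2. Among the 10 that fell were the lectin chaperone gene CRT1 (-1.4 ± 0.07), the co-chaperone gene P58IPK (-1.16 ± 0.1) and the HSP70 chaperone gene BIP1 (-0.37 ± 0.07), and 6 of the 20 were not called. The list was not called as a set (camera adjusted p 0.76), its median of -0.16 and mean of 0.16 differ in sign, and the counts were the same adjusted over the list alone. The ERAD list, with 4 of 10 higher and 2 lower, was not called either (camera adjusted p 0.4).

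Cell-type and hormone lists also changed in bz1728 root. In the root hair list 14 of 15 members rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p 4.1e-22; 0.013 with an estimated correlation), with the cell wall genes PRP1 up by 4.27 ± 0.24 and EXT12 at 608 ± 127 CPM against 32.9 ± 5.21. In the endodermis and suberin list 17 of 20 members fell and 1 rose, the same adjusted over the list alone, with the suberin gene GPAT5 at -1.6 ± 0.14 (camera adjusted p 5.7e-10, adjusted p = 0.16 with an estimated correlation). Of 11 jasmonate members 9 rose and 2 fell, the same adjusted over the list alone, with TAT3 up by 8.03 ± 0.65 and JAZ10 by 5.2 ± 0.36 (camera adjusted p 4.9e-07, adjusted p = 0.099 with an estimated correlation). In the photosynthesis list 16 of 24 members fell and 0 rose, the same adjusted over the list alone (camera adjusted p 0.00029, adjusted p = 0.45 with an estimated correlation).

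Ethylene, auxin and phosphate starvation members rose more often than they fell. Of 12 ethylene members 7 rose and 1 fell (8 and 1 adjusted over the list alone), among them the ethylene receptor gene ERS1 by 0.56 ± 0.08 (camera adjusted p 0.00067, adjusted p = 0.099 with an estimated correlation). Of 12 auxin response members 7 rose and 2 fell, the same adjusted over the list alone (camera adjusted p 0.034, adjusted p = 0.21 with an estimated correlation). Of 12 phosphate starvation members 7 rose and 2 fell (7 and 3 adjusted over the list alone), with the ribonuclease gene RNS1 up by 4.58 ± 0.34 and the transporter gene PHT1;1 down (-1.19 ± 0.11), at a camera adjusted p of 0.042 (adjusted p = 0.45 with an estimated correlation). Among the most reduced genes, the cytochrome P450 genes CYP76G1 and CYP712A2 were at least 65.6-fold and at least 61.6-fold lower, with 0 counts in bz1728. In total edgeR called 7290 genes, 3417 higher and 3873 lower, and 2000 of them changed at least 2-fold.

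**Figure D2:**
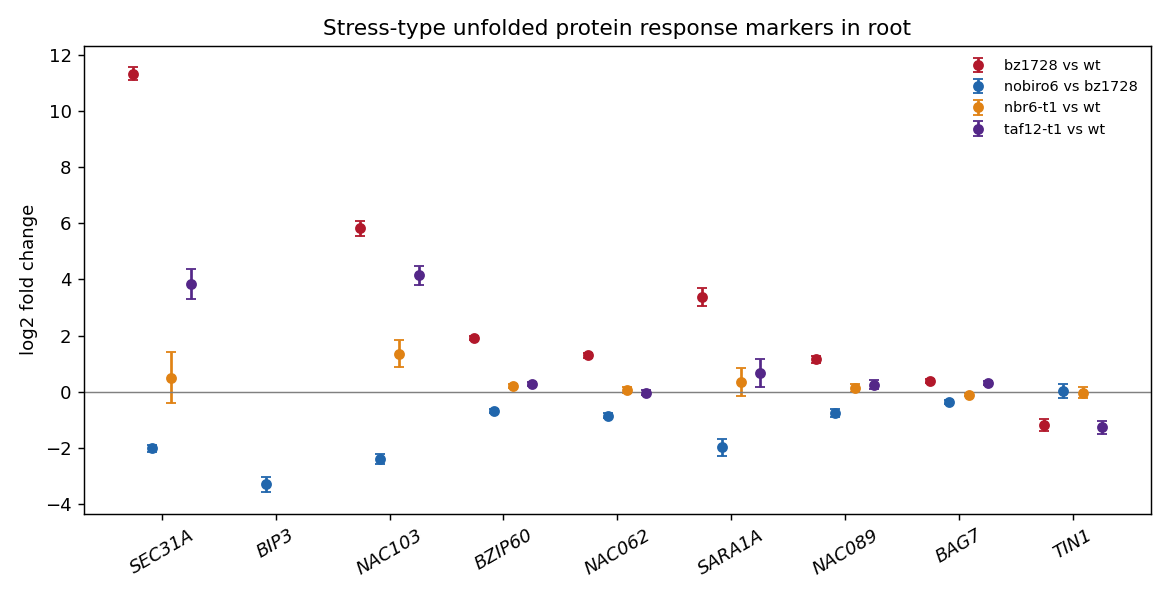
Log2 fold change ± approximate SE (vertical axis) of the 9 stress-type UPR markers (horizontal axis) in 4 root comparisons, n = 4 libraries per group. BIP3 is drawn for nobiro6 against bz1728 alone because wt root held 0 counts. SEC31A lies at 11.32 in bz1728 against wt and at -2.02 in nobiro6 against bz1728.

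In root, nobiro6 was compared with bz1728. Because libraries labelled nobiro6 hold BZIP28 transcript (13.9 CPM in root, 26.9 in shoot) and bz1728 libraries hold 0, this comparison does not separate the suppressor mutation from the difference in BZIP28 and its neighbours, here and in each comparison that uses it. All stress-type markers but TIN1 (0.02 ± 0.25, not called) fell, so 8 of 9, also adjusted over the list alone. SEC31A moved from 790 ± 92.5 to 194 ± 25.9 CPM (-2.02 ± 0.11), NAC103 fell by 2.4 ± 0.19, BIP3 by 3.3 ± 0.28 and BZIP60 by 0.69 ± 0.07 (camera adjusted p for the list 1.2e-12; 0.0012 with an estimated correlation). The ER folding list had 12 of 20 members lower and 2 higher, also adjusted over the list alone, with ERO1 down by 1.95 ± 0.13 on the log2 scale and CRT3 up by 0.58 ± 0.08 (camera adjusted p 1e-05, adjusted p = 0.19 with an estimated correlation).

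Iron deficiency genes formed a further group that fell in nobiro6 root. Of 14 members 13 were lower than in bz1728 and 0 higher, the same adjusted over the list alone (camera adjusted p 1e-18; 0.0015 with an estimated correlation). The transporter gene OPT3 fell by 2.57 ± 0.1, the regulator gene BHLH39 by 2.63 ± 0.22 and the coumarin synthesis gene F6'H1 by 1.55 ± 0.11. Ethylene members fell in 7 of 12 cases and rose in 0, the same adjusted over the list alone, with CHIB at -2.43 ± 0.12 and HEL at -1.31 ± 0.12 (camera adjusted p 1e-08; 0.0042 with an estimated correlation). Of 11 jasmonate members 9 fell and 0 rose, the same adjusted over the list alone, JAZ10 by 3.34 ± 0.31 (camera adjusted p 1.2e-08; 0.038 with an estimated correlation).

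Other lists called in this comparison lost the call with an estimated correlation. Root hair members fell in 9 of 15 cases (camera adjusted p 6.5e-05, adjusted p = 0.19 with an estimated correlation), with EXT12 at -1.37 ± 0.17. Photosynthesis members rose in 16 of 24 cases, 17 adjusted over the list alone, with LHCA1 up by 1.22 ± 0.16 (camera adjusted p 1.7e-07, adjusted p = 0.19 with an estimated correlation). Salicylic acid members fell in 6 of 12 cases (camera adjusted p 0.014, adjusted p = 0.19 with an estimated correlation), and suberin members rose in 7 of 20 and fell in 3, or 8 and 3 adjusted over the list alone (0.011, adjusted p = 0.49 with an estimated correlation). Phosphate starvation members fell in 6 of 12 and rose in 1, or 6 and 2 adjusted over the list alone (camera adjusted p 0.0016, adjusted p = 0.19 with an estimated correlation), and root-abundant members fell in 4 of 7 and rose in 1 (0.0043, adjusted p = 0.14 with an estimated correlation).

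Among the largest decreases in nobiro6 root were BGAL9 (AT2G32810), a beta-galactosidase gene, at 0.345 ± 0.429 CPM against 49.4 ± 6.29 (-7 ± 0.26), and the carbonic anhydrase gene BCA3 (-6.25 ± 0.26). Among the largest increases were the sugar transporter gene SWEET11 (4.45 ± 0.62) and the signalling peptide gene CLE6 (2.7 ± 0.3). Altogether edgeR called 5938 genes, 2395 higher and 3543 lower.

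The share of bz1728 changes that nobiro6 moved back was counted gene by gene. Of the 3417 genes higher in bz1728 root, 1624 (47.5%) were lower in nobiro6 than in bz1728, where 646 are expected for independent lists. Of these, 1015 were not called against wt, 257 stayed higher than wt and 352 were lower than wt. Of the 3873 genes lower in bz1728 root, 1122 (29%) were higher in nobiro6, where 495 are expected, and of these 667 were not called against wt, 388 stayed lower than wt and 67 were higher than wt. Of the lower and higher genes 575 and 93 moved further from wt in nobiro6, where 732 and 437 are expected for independent lists. Sharing the bz1728 libraries by itself lowers such numbers, and they were not counted with split libraries, so they are not read as a reversal. With the bz1728 libraries split between the comparisons, 1136 to 1227 and 583 to 787 genes overlapped, where 400 and 264 are expected. Across genes, which are not independent replicates, the changes had a covariance of -0.252 in root, against -0.235 with split libraries and -0.0184 in simulations, and -0.236 in shoot, against -0.223 and -0.0292. The correlation r was -0.49 in root and -0.66 in shoot, and -0.44 and -0.53 with split libraries. Sharing the bz1728 libraries alone gave -0.48 and -0.53 in simulations, so the unsplit r is not read as a reversal.

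What remained different from wild type in root was read from nobiro6 against wt. Stress-type markers stayed higher in 7 of 9 cases, with SEC31A up by 9.3 ± 0.25 and BZIP60 by 1.23 ± 0.08, and TIN1 lower (camera adjusted p 6.8e-11; 0.00044 with an estimated correlation). All 14 iron deficiency members were lower, with the nicotianamine synthase gene NAS2 at 5.19 ± 2.67 CPM against 76.6 ± 11.1 (camera adjusted p 6.6e-14; 0.0051 with an estimated correlation). For both lists the counts adjusted over the list alone were the same. The call was lost with an estimated correlation for root hair (11 of 15 higher and 1 lower, 12 and 1 adjusted over the list alone; adjusted p = 0.076), suberin (1 higher and 16 lower of 20, 1 and 17 adjusted over the list alone; adjusted p = 0.41) and ER folding (6 higher and 12 lower of 20; adjusted p = 0.58). It was also lost for salicylic acid (9 of 12 lower, 10 adjusted over the list alone; adjusted p = 0.16), root-abundant genes (6 of 7 lower; adjusted p = 0.076) and TFIID and SAGA subunits (5 higher and 1 lower of 23; adjusted p = 0.076). The heat shock list was not called (0 higher and 3 lower of 9, camera adjusted p 0.37). In total 8024 genes were called, 3546 higher and 4478 lower, more than for bz1728 against wt.

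In shoot, the phosphate starvation list was higher in bz1728 than in wt. Of its 14 members 12 rose and 0 fell, the same adjusted over the list alone, with the phosphatase gene PAP17 at 238 ± 55.5 CPM against 36.4 ± 10.1 in wt and SPX1 up by 3.04 ± 0.39 (camera adjusted p 1.5e-18; 0.025 with an estimated correlation). IPS1, a non-coding RNA of the phosphate response, was among the genes with the largest increase (4.84 ± 0.7). Stress-type markers rose in 4 of 9 cases and fell in 0 (5 and 1 adjusted over the list alone), with NAC103 up by 3.97 ± 0.37, SEC31A by 3.08 ± 0.3 and BZIP60 by 0.9 ± 0.11, and BIP3 not called at -3.2 ± 1.34 (camera adjusted p 6.8e-08; 0.00049 with an estimated correlation). Auxin response members fell in 5 of 8 cases and rose in 0 (6 and 0 adjusted over the list alone), with IAA1 at 6.38 ± 1.37 CPM against 19.6 ± 3.79 (camera adjusted p 2.9e-05; 0.011 with an estimated correlation).

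ER folding members fell in 11 of 20 shoot cases and rose in 3 (13 and 3 adjusted over the list alone), with BIP2 at -1.08 ± 0.13 and CRT1 at -0.94 ± 0.07 (camera adjusted p 6.8e-08, adjusted p = 0.16 with an estimated correlation). Photosynthesis members fell in 13 of 24 cases, 15 adjusted over the list alone, with LHCB2.1 at -0.66 ± 0.09 (camera adjusted p 4.2e-08, adjusted p = 0.31 with an estimated correlation). Salicylic acid and immunity members fell in 8 of 15 cases, 10 adjusted over the list alone, with the pathogenesis-related gene PR2 at -6.64 ± 1.55 (camera adjusted p 3.1e-05, adjusted p = 0.31 with an estimated correlation). Iron deficiency members rose in 4 of 8 cases, also adjusted over the list alone, BHLH39 by 4.81 ± 0.86 and BHLH38 by 4.72 ± 0.84 (camera adjusted p 0.0047, adjusted p = 0.34 with an estimated correlation). The BHLH39 level spread from library to library, at 36.2 ± 33.7 CPM in bz1728. The defensin gene PDF1.2c was at least 72.4-fold lower, with 0 counts in bz1728. The edgeR test called 3098 genes in shoot, 1460 higher and 1638 lower.

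In shoot, fewer stress-type markers were called in nobiro6 against bz1728. NAC103 fell by 1.57 ± 0.32, NAC089 by 0.54 ± 0.12 and SARA1A by 0.67 ± 0.21 against bz1728, while SEC31A (-0.63 ± 0.26) and BZIP60 (0.07 ± 0.11) were not called, and the list was not called (camera adjusted p 0.13, 3 lower of 9, and 4 adjusted over the list alone). The change of this list differed between root and shoot by a median of -0.77 (camera adjusted p 0.00014; 0.0048 with an estimated correlation). BGAL9 was again among the most reduced genes, at 1.08 ± 0.39 CPM against 46.4 ± 3.49 (-5.41 ± 0.16). IAA1 rose by 1.56 ± 0.18, and the abscisic acid synthesis gene NCED3 fell by 2.64 ± 0.46.

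List calls in shoot nobiro6 against bz1728 did not hold with an estimated correlation. Photosynthesis members rose in 10 of 24 cases (11 higher and 1 lower adjusted over the list alone), LHCB2.1 by 0.69 ± 0.09 (camera adjusted p 0.00081, adjusted p = 0.58 with an estimated correlation). Phosphate starvation members fell in 4 of 14 cases, 6 adjusted over the list alone, PAP17 by 1.26 ± 0.27 (camera adjusted p 0.0016, adjusted p = 0.5 with an estimated correlation). Iron deficiency members fell in 6 of 8 cases, also adjusted over the list alone, BHLH39 by 4.87 ± 0.96 (camera adjusted p 0.0016, adjusted p = 0.42 with an estimated correlation). ABA, cold and drought members fell in 5 of 15 cases, 7 adjusted over the list alone (camera adjusted p 0.0016, adjusted p = 0.5 with an estimated correlation). Auxin response members rose in 3 of 8 and fell in 1, or 4 and 1 adjusted over the list alone (camera adjusted p 0.013, adjusted p = 0.34 with an estimated correlation), and root-abundant members fell in 2 of 4 (0.024, adjusted p = 0.36 with an estimated correlation). In total edgeR called 3644 genes, 1412 higher and 2232 lower.

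Of the 1460 genes higher in bz1728 shoot, 886 (60.7%) were lower in nobiro6 than in bz1728, where 187 are expected for independent lists, and 736 of them were not called against wt. Of the 1638 genes lower in bz1728 shoot, 692 (42.2%) were higher in nobiro6, where 133 are expected, and 648 were not called against wt. In shoot 36 of the lower and 4 of the higher genes moved further from wt, where 210 and 119 are expected, with the same limit as in root. With split bz1728 libraries 399 to 469 and 229 to 272 genes overlapped, where 75 and 39 are expected. Without shoot bz1728 replicate 2 the count of 692 moved to 402. Against wt, nobiro6 shoot had 637 genes higher and 1473 lower, 2110 in all and 1295 with libraries thinned to an equal depth. Stress-type markers stayed higher in 4 of 9 cases, SEC31A by 2.45 ± 0.31 (camera adjusted p 0.00068; 0.019 with an estimated correlation). Phosphate starvation (9 of 14 higher, 10 adjusted over the list alone) and ER folding (3 higher and 11 lower of 20, 4 and 12 adjusted over the list alone) were called by camera (1.8e-08 and 0.00039) and lost the call with an estimated correlation (adjusted p = 0.21 and 0.5). So did salicylic acid (1 of 15 lower, 3 adjusted over the list alone; adjusted p = 0.68), ABA, cold and drought (4 of 15 lower; adjusted p = 0.68) and root-abundant genes (2 of 4 lower; adjusted p = 0.15).

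In root, iron deficiency genes were lower in the TAF12B T-DNA line nbr6-t1 than in wt, though TAF12B itself was not called there. All 14 members fell, also adjusted over the list alone, with the ferric reductase gene FRO2 at 15.8 ± 5.33 CPM against 122 ± 54.3 (-2.87 ± 0.42), CYP82C4 at 3.51 ± 2.03 against 82.2 ± 55.2 and OPT3 at -0.84 ± 0.1 (camera adjusted p 5.2e-20; 0.0015 with an estimated correlation). Root-abundant genes fell in 6 of 7 cases and rose in 0, also adjusted over the list alone, with the beta-glucosidase gene BGLU21 at 353 CPM against 624 and the aquaporin gene TIP2;3 at -1.07 ± 0.22 (camera adjusted p 7.2e-06; 0.023 with an estimated correlation). In the stress-type list 1 of 9 members rose (NAC103 by 1.35 ± 0.48; 0 adjusted over the list alone) and the list was not called (camera adjusted p 0.38), and in the ER folding list 1 of 20 members rose (CRT3 by 0.36 ± 0.08; camera adjusted p 0.62).

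Photosynthesis members rose in 13 of 24 nbr6-t1 root cases and fell in 0 (16 and 0 adjusted over the list alone), with LHCA1 up by 0.75 ± 0.14 (camera adjusted p 1.2e-07, adjusted p = 0.38 with an estimated correlation). Root hair members rose in 6 of 15 cases and fell in 1 (7 and 3 adjusted over the list alone), the regulator genes RSL4 by 1.19 ± 0.19 and RHD6 by 0.74 ± 0.14 (camera adjusted p 0.023, adjusted p = 0.55 with an estimated correlation). FRO5 fell by 4.23 ± 0.33 and the lectin gene PP2-A3 by 3.27 ± 0.23, while the metallothionein gene MT2A rose by 1.81 ± 0.21. Called by edgeR were 3836 genes, 1305 higher and 2531 lower. TAF12B itself was not called in these root libraries, so the changes are not tied to a lower TAF12B transcript. Other loci, read after their values were seen, also set lines apart in root. AT1G75945 held 0 counts in nbr6-t1 and taf12-t1, against 189 in wt, 119 in bz1728 and 117 in nobiro6. AT1G64795 stood at 9.32 ± 1.07 CPM in wt, 0.515 ± 0.876 in nobiro6 and 1.23 ± 1.91 in nbr6-t1. It held 0 counts in bz1728 and taf12-t1, so it was low in every line but wt. Each comparison against wt therefore includes this locus. Whether such differences bear on the changes was not tested.

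In nbr6-t1 shoot, ABA, cold and drought members fell in 4 of 15 cases and rose in 0 (5 and 0 adjusted over the list alone), with ERD10 at -1 ± 0.22 and RD20 at -1.98 ± 0.57 (camera adjusted p 9.3e-05, adjusted p = 0.69 with an estimated correlation). It was the only list called there among the 16 tested. The beta-glucosidase gene BGLU28 fell by 4.1 ± 0.87, LSU1 by 2.87 ± 0.52 and the sugar transporter gene SWEET13 by 2.86 ± 0.3, while the copper transporter gene COPT2 rose by 1.1 ± 0.19. In total 1303 genes were called, 271 higher and 1032 lower, and 741 with libraries thinned to an equal depth.

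The comparison of nobiro6 with bz1728 and that of nbr6-t1 with wt shared changes, in the same direction. In root 1489 genes were lower both in nobiro6 against bz1728 and in nbr6-t1 against wt, where 478 are expected for independent lists, and 518 were higher in both, where 167 are expected. In shoot 707 were lower in both and 120 higher, where 133 and 22 are expected. Without shoot nbr6-t1 replicate 4 the count of 120 moved to 79. These comparisons share no library. Across genes the log2 fold changes had r = 0.48 and rho = 0.47 in root and 0.46 and 0.45 in shoot, and 195 and 12 genes were called in opposite directions, where 570 and 119 are expected.

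The changes of nobiro6 against bz1728 and of nbr6-t1 against wt were unequal for part of the genes. In root 2066 genes differed, 902 with a higher and 1164 with a lower change in nobiro6. BGAL9 had a change lower by 7.43 ± 0.3 in root and 5.71 ± 0.19 in shoot, and the arabinogalactan protein gene FLA8 a change higher by 1.37 ± 0.11 in root. Stress-type markers differed downward in 6 of 9 cases (camera adjusted p 7.1e-08; 0.0068 with an estimated correlation), jasmonate members in 7 of 11 (2.8e-09; 0.04 with an estimated correlation) and ethylene members in 5 of 12 (3e-07; 0.017 with an estimated correlation). Adjusted over the list alone, these counts were 8, 9 and 7. Called by camera but lost with an estimated correlation were ER folding (9 of 20 lower, 9 lower and 1 higher adjusted over the list alone; adjusted p = 0.17), root hair (10 of 15 lower, also adjusted over the list alone; adjusted p = 0.062) and suberin (7 higher and 2 lower of 20, 11 and 2 adjusted over the list alone; adjusted p = 0.34). So were iron deficiency (1 higher and 4 lower of 14, 1 and 5 adjusted over the list alone; adjusted p = 0.19), phosphate starvation (1 higher and 4 lower of 12, 1 and 5 adjusted over the list alone; adjusted p = 0.12) and auxin response (3 of 12 lower, 5 adjusted over the list alone; adjusted p = 0.095). In shoot 221 genes differed, 95 higher and 126 lower. Auxin response members differed upward in 2 of 8 shoot cases, also adjusted over the list alone (camera adjusted p 3.2e-06; 0.0077 with an estimated correlation). Photosynthesis (3 of 24 higher, 10 adjusted over the list alone), phosphate starvation (0 of 14, 9 lower adjusted over the list alone), iron deficiency (0 of 8, also adjusted over the list alone) and salicylic acid (0 of 15, 1 higher adjusted over the list alone) lost the call in shoot with an estimated correlation (camera adjusted p 0.49, 0.31, 0.49 and 0.68). DESeq2 called 450 there, and leaving out a library moved the count to between 118 (without shoot nbr6-t1 replicate 2) and 367 (without shoot nobiro6 replicate 3), with 128 without shoot nobiro6 replicate 1 and 134 without shoot bz1728 replicate 2.

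In root, photosynthesis genes were lower in taf12-t1 than in wt, though the TAF12 transcript was higher there (20.6 ± 3.89 against 10.2 ± 0.512 CPM). Of 24 members 18 fell and 0 rose (18 and 1 adjusted over the list alone), with LHCA4 at 26.8 CPM against 75.1 (-1.51 ± 0.1) and PSBO1 at -1.76 ± 0.13 (camera adjusted p 3.1e-16, adjusted p = 0.11 with an estimated correlation). Summed over the list, the root level was 310 ± 45.7 CPM in taf12-t1 and 710 ± 20.9 in wt, and the summed myrosinase genes TGG1 and TGG2, used as shoot markers, stood at 1.25 ± 1.69 and 0.792 ± 0.806 CPM. ER folding members rose in 15 of 20 cases and fell in 0, also adjusted over the list alone, with BIP1 up by 0.61 ± 0.07 and BIP2 at 952 CPM against 603 (camera adjusted p 7e-07, adjusted p = 0.24 with an estimated correlation).

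Stress-type markers rose in 5 of 9 taf12-t1 root cases and fell in 1, also adjusted over the list alone, with NAC103 up by 4.14 ± 0.33 and SEC31A by 3.84 ± 0.54 (camera adjusted p 0.0076, adjusted p = 0.11 with an estimated correlation). Cell cycle members rose in 12 of 20 cases and fell in 0 (13 and 0 adjusted over the list alone), among them PCNA1 by 0.88 ± 0.11 (camera adjusted p 0.00016, adjusted p = 0.18 with an estimated correlation). TFIID and SAGA members rose in 9 of 23 cases and fell in 2, with TAF1 up by 0.75 ± 0.07 (camera adjusted p 0.0076, adjusted p = 0.083 with an estimated correlation). ABA, cold and drought members rose in 6 of 14 and fell in 1, KIN1 by 1.64 ± 0.22 (camera adjusted p 0.0026, adjusted p = 0.3 with an estimated correlation), and auxin response members rose in 7 of 12, or 8 adjusted over the list alone (0.026, adjusted p = 0.23 with an estimated correlation).

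Among the most changed genes of taf12-t1 root, FLC, a repressor of flowering, rose by 4.42 ± 0.52 (10 CPM against 0.38), and AGL20, a promoter of flowering, fell by 3.55 ± 0.25 (3.18 CPM against 35.7). MRD1 stood at 21.6 ± 2.62 CPM against 2 counts in wt root, a ratio of 263 with a counting interval of 72.3 to 2180. Altogether edgeR called 7356 genes in root, 3651 higher and 3705 lower.

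In taf12-t1 shoot, stress-type markers rose in 5 of 9 cases and fell in 0, SEC31A by 3.32 ± 0.29 and NAC103 by 2.98 ± 0.4 (camera adjusted p 0.009, adjusted p = 0.08 with an estimated correlation). ER folding members rose in 10 of 20 cases, BIP1 by 0.66 ± 0.1 (camera adjusted p 0.024, adjusted p = 0.7 with an estimated correlation). TFIID and SAGA members rose in 9 of 22 cases and fell in 2, TAF1 by 1.19 ± 0.06 (camera adjusted p 0.009, adjusted p = 0.087 with an estimated correlation). Root-abundant members rose in 4 of 4 cases, PBP1 by 0.88 ± 0.14 (camera adjusted p 0.011, adjusted p = 0.23 with an estimated correlation), and phosphate starvation members in 7 of 14, SQD1 by 1.37 ± 0.18 (0.009, adjusted p = 0.7 with an estimated correlation). For these 5 lists the counts adjusted over the list alone were the same. Photosynthesis members fell in 14 and rose in 6 of 24 cases, with LHCB3 at -0.89 ± 0.1 and GAPA at 0.53 ± 0.07 (camera adjusted p 0.024, adjusted p = 0.89 with an estimated correlation).

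Cell cycle members rose in 9 of 17 taf12-t1 shoot cases, 10 adjusted over the list alone, the cytokinesis gene KN by 0.79 ± 0.14 (camera adjusted p 0.024, adjusted p = 0.7 with an estimated correlation). The clock gene ELF4 rose by 4.46 ± 0.28, the flavonoid pathway regulator gene TT8 by 4.19 ± 0.51 and the meiotic crossover gene HEI10 by 3.79 ± 0.3, while DOT3 fell by 3.42 ± 0.35. The edgeR test called 7063 genes, 3521 higher and 3542 lower.

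The T-DNA lines of the TFIID paralogs were then set side by side. Against nbr6-t1, taf12-t1 root had lower photosynthesis genes in 21 of 24 cases, also adjusted over the list alone (camera adjusted p 3.6e-25; 0.046 with an estimated correlation), and higher iron deficiency genes in 12 of 14, 13 adjusted over the list alone (9.7e-08; 0.046 with an estimated correlation). ER folding (14 higher, 1 lower), cell cycle (15 higher), suberin (9 higher), ABA (8 higher) and heat shock (1 higher, 4 lower) were called in root, and stress-type markers (4 of 9 higher), cell cycle (10 of 17), ABA (8 of 15) and root-abundant genes (4 of 4) in shoot, but none of these with an estimated correlation (camera adjusted p 0.11 to 0.64). In root 8854 genes differed, 4636 higher and 4218 lower in taf12-t1, and in shoot 8192, 4269 higher and 3923 lower. Of the genes changed against wt, 336 were higher and 717 lower in both lines in root, where 254 and 500 are expected for independent lists. In shoot 82 were higher and 245 lower in both, where 55 and 210 are expected. With the shared wt libraries split, 98 to 181 and 372 to 438 genes overlapped in root, where 100 and 267 are expected, and 21 to 42 and 104 to 136 in shoot, where 19 and 99 are expected. Without root wt replicate 3 the count of 336 moved to 209, and without root nbr6-t1 replicate 4 to 211. Across genes, which are not independent replicates, r was 0.13 and rho 0.09 in root and 0.01 and -0.02 in shoot. Sharing the wt libraries alone gave r = 0.44 in simulations, and with split libraries r was 0.07 and -0.08, so the printed r is not read as a common change. The covariance was 0.0341 in root, against 0.0199 with split libraries (0.0148 to 0.0248) and 0.0173 in simulations, and 0.00342 in shoot, against -0.0219 (-0.0365 to -0.0015) and 0.0229. In root and shoot 744 and 311 genes were called in opposite directions, where 751 and 264 are expected for independent lists.

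**Figure D3:**
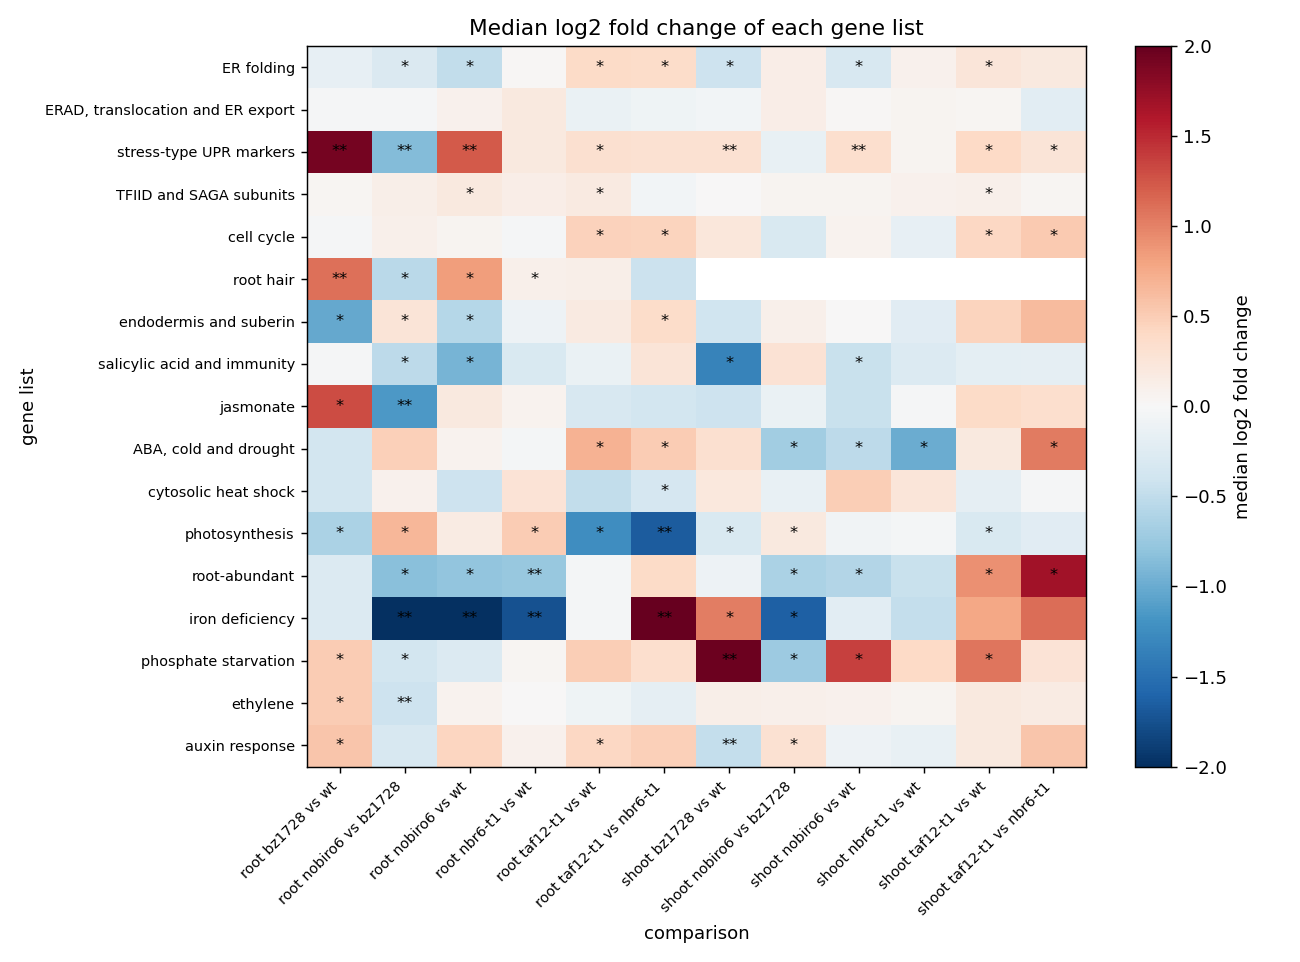
Median log2 fold change of each of the 17 gene lists (vertical axis) in 12 comparisons (horizontal axis), with colours limited to -2 and 2, an asterisk for a camera adjusted p under 0.05, a pair of asterisks where the call also held with an estimated correlation, and a blank where a list was not tested. The iron deficiency list in root was called lower in nobiro6 against bz1728, in nobiro6 against wt and in nbr6-t1 against wt.

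Root and shoot responses were compared by interaction. For bz1728 against wt 4594 of 20015 genes differed between tissues, 2411 with a higher and 2183 with a lower change in root. The stress-type markers had the higher change in root in 8 of 9 cases and the lower change in 1 (camera adjusted p 2e-08; 2.2e-05 with an estimated correlation), and auxin response members had the higher change in 5 of 12 cases and the lower in 1 (0.0013; 0.027 with an estimated correlation). For nobiro6 against bz1728 3170 genes differed, 1749 higher and 1421 lower in root, among them the ethylene list with 5 of 12 lower (camera adjusted p 2.8e-06; 0.012 with an estimated correlation). For taf12-t1 against wt 4072 genes differed, 1961 higher and 2111 lower, with 6 of 7 root-abundant members lower (camera adjusted p 6.3e-06; 0.012 with an estimated correlation). For nbr6-t1 against wt 481 genes differed, 355 higher and 126 lower. On log2(TPM + 1) with limma-trend that count was 765 (282 higher and 483 lower), and with libraries thinned to an equal depth it was 190, while the count for bz1728 was then 2944 and that for taf12-t1 2591.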

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

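The tests of explanations for the 3 patterns and the counts over other splits of the samples were chosen after the results had been seen, while the interactions and the search for distant libraries were planned.

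BZIP28 had 243 counts in root and 523 in shoot over the libraries labelled nobiro6, a line described as carrying its mutation in the bz1728 background. Wild-type RNA in these libraries is argued against by BZIP17, of which no shoot nobiro6 library lay more than 2.85% of the way from bz1728 to wt, while BZIP28 lay 77.9 ± 9.46% of the way in shoot and 19.4 ± 4.63% in root. Reads from another gene are argued against by 0 counts of BZIP28 over the 8 bz1728 libraries. A candidate explanation is a lesion at BZIP28 in the bz1728 libraries that the nobiro6 libraries lack, since the next gene AT3G10810 had 1 count over the 8 bz1728 libraries and 125% of the wt level in nobiro6 root. It was found from these data and does not by itself account for the lower BZIP28 level in root, the insertion positions were not analysed here, and no biological explanation was tested.

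TAF12B in nbr6-t1 was lower than wt in shoot and not called in root, with a difference between tissues of 1.99. Wild-type RNA in the root libraries labelled nbr6-t1 is argued against by 418 genes lower in both tissues, where 98 are expected for independent lists. Reads from another gene are argued against by 0.219% of the TAF12B 31-mers being shared. A transcript read through or started in the insertion may differ between tissues, and the value of 1.99 leaves this open because the tables hold 1 value per gene. A difference between root and shoot in the use of TAF12B stays open too and was not tested.

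The photosynthesis list in root libraries ranged from 310 ± 45.7 CPM in taf12-t1 to 962 ± 60.3 in nbr6-t1, with 710 ± 20.9 in wt. Carry-over of whole shoot tissue into the root samples is argued against by the abundant shoot markers TGG1 and TGG2, 2 of 10 markers read, which reached at most 0.035% of their shoot level where the list stood at 0.253 to 0.846%. In wt root each of the other markers stood at a higher share of its shoot level than the list did. The argument therefore rests on TGG1 and TGG2 alone. KAT1, MYB60 and GL1 were low in wt root, at 0.351, 0.219 and 0.0422 CPM. PDF1 stood higher in root (37.7 CPM in wt, 10.7 in bz1728, 55.8 in nobiro6, 59.4 in nbr6-t1 and 80 in taf12-t1), as did FDH (35.9, 14.4, 33, 32.6 and 53.7). PDF1 and FDH were lower in bz1728 root than in wt and nobiro6 root, as the list was. They were highest in taf12-t1, where the list was lowest. Carry-over of a part of the shoot poor in TGG1 and TGG2, and a difference between genotypes in root plastid transcripts, stay open and were not tested.

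For the pairwise counts of changed genes the real grouping alone gave as many genes, 1 of 35 splits each. This is the smallest share that 35 splits can give, and it was not adjusted over the comparisons. Chance is argued against and not excluded. In root the real counts and the highest other split were 7290 and 2 for bz1728 against wt, 5938 and 289 for nobiro6 against bz1728, 8024 and 1 for nobiro6 against wt, 3836 and 0 for nbr6-t1, 7356 and 0 for taf12-t1, and 8854 and 0 for taf12-t1 against nbr6-t1. In shoot they were 3098 and 47, 3644 and 30, 2110 and 83, 1303 and 186, 7063 and 0, and 8192 and 0 in the same order.

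For the interactions 100 splits were drawn. At first 30 were drawn for those between tissues and 60 for those between backgrounds, and the number was raised to 100 for all 6 after the first shares had been seen. In the first draws 2 of 30 splits for taf12-t1 and 3 of 60 for the shoot background were as large as the real one, the real one included. At 100 splits the real count, the highest other count and the number as large were 4594, 3068 and 1 for the bz1728 tissue interaction. For nobiro6 against bz1728 they were 3170, 3056 and 1, and for the root background 2066, 7271 and 3. For the taf12-t1 tissue interaction (4072, 4949 and 2) and the shoot background (221, 2521 and 4) the share was 0.05 or more in the first draws. At 100 splits it was under 0.05. The nbr6-t1 tissue interaction (481, 1236 and 4) was also under 0.05 at 100 splits. Its count was 190 in thinned libraries and 329 without shoot nbr6-t1 replicate 1. The splits mix the genotypes of at least 1 pair, so they remove genotype differences together with the interaction. They therefore cannot exclude chance for an interaction, and it is not taken as excluded for any of them. The splits with more genes than the real one keep the genotypes of 1 pair parted and so carry that structure of the samples, while splits with neither pair intact gave at most 51 (bz1728), 180 (nobiro6 against bz1728), 341 (nbr6-t1), 344 (taf12-t1), 0 (root background) and 8 (shoot background) genes. The labels give no batches.

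Differences between root and shoot in whole lists are medians of root minus shoot, called by camera. For bz1728 they were 0.32 for ER folding, 1.09 for stress-type markers, 1.66 for jasmonate, 0.73 for ethylene, 1.18 for auxin response, -0.27 for photosynthesis and -1.55 for phosphate starvation. For nobiro6 against bz1728 they were -0.39 for ER folding, -0.77 for stress-type markers, 0.27 for cell cycle, -1.35 for salicylic acid, -1.86 for jasmonate, 1.02 for ABA, cold and drought, 0.49 for photosynthesis, -0.54 for ethylene and -0.42 for auxin response. For nbr6-t1 they were 1.19 for ABA, cold and drought, 0.6 for photosynthesis, -1.23 for iron deficiency and -0.36 for phosphate starvation. For taf12-t1 they were -0.78 for photosynthesis and -1.13 for root-abundant genes. With an estimated correlation the call held for stress-type markers and auxin response in bz1728 (camera adjusted p 2.2e-05 and 0.027), for stress-type markers, ethylene and auxin response in nobiro6 against bz1728 (0.0048, 0.012 and 0.018) and for root-abundant genes in taf12-t1 (0.012).

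Single genes also differed between root and shoot in log2 change, with edgeR. For bz1728 these were EMB1030 (2.38 ± 0.15), sks9 (3.93 ± 0.31), AST91 (2.52 ± 0.22), SVB (1.64 ± 0.14), HOL1 (-1.92 ± 0.12), CSLA02 (-1.78 ± 0.12), TPS1 (-1.77 ± 0.12) and MSL5 (-3.18 ± 0.24). For nobiro6 against bz1728 the genes were TPS1 (1.45 ± 0.13), TLL1 (2.71 ± 0.21), FLP (2.01 ± 0.21), SWEET11 (5.29 ± 0.51), NIT1 (-2.39 ± 0.15), AST91 (-4.31 ± 0.31), BLH2 (-2.81 ± 0.26) and TAF12B (0.55 ± 0.15). For nbr6-t1, beside TAF12B, they were ZW9 (3.60 ± 0.4), FBP (1.01 ± 0.13), ANNAT3 (2.18 ± 0.31), FLS1 (-1.29 ± 0.21), XTH16 (-1.69 ± 0.29) and HMGS (-0.60 ± 0.11). For taf12-t1 they were EMB1030 (1.98 ± 0.16), PKp3 (1.28 ± 0.12), DGR2 (1.43 ± 0.14), XTH4 (1.33 ± 0.14), PSBO2 (-2.01 ± 0.18), AGT (-2.81 ± 0.24), PSBR (-1.52 ± 0.14), PSBO1 (-1.73 ± 0.16) and TAF12 (1.55 ± 0.23).

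In 12 of 233 groups of 4 libraries 1 library lay far from the other 3, and 12 are expected by chance at 5%. Shoot nbr6-t1 replicate 1 had 7698 transcripts at 0. BZIP17 stood at 38.9 CPM in shoot taf12-t1 replicate 1 (others 42.8 to 43.6), and BZIP28 at 8.95 CPM in root nobiro6 replicate 4 (others 15.1 to 16.1). In mean log2 CPM, the ER folding list stood at 5.22 in shoot bz1728 replicate 3 (others 5.17 to 5.18) and 5.39 in shoot nobiro6 replicate 1 (5.24 to 5.26). The ERAD list stood at 4.37 in shoot bz1728 replicate 4 (4.46 to 4.47) and 5.93 in root nobiro6 replicate 4 (5.8 to 5.81). In shoot wt, replicate 1 stood at 3.35 for cell cycle (3.09 to 3.12) and 2.58 for jasmonate (4.14 to 4.36), and replicate 4 at 3.82 for TFIID and SAGA (3.92 to 3.94) and 4.73 for ethylene (4.5 to 4.53). The phosphate starvation list stood at 4.51 in root nobiro6 replicate 3 (4.4 to 4.41).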

How the results depend on the processing

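Thinning all libraries to an equal depth was chosen after the results had been seen, and the other alternatives here were planned.

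With RLE or upper-quartile factors, no filter, the compared groups alone or the replicate block, each count recomputed stayed within 1.5 times. With DESeq2 the shoot background interaction moved from 221 to 450 genes, and on log2(TPM + 1) the nbr6-t1 tissue interaction moved from 481 (355 higher, 126 lower) to 765 (282 higher, 483 lower), so the more frequent direction changed; the cause was not tested.

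Thinned libraries hold fewer counts, and fewer genes were called. Shoot nobiro6 against wt moved from 2110 to 1295 and shoot nbr6-t1 from 1303 to 741. The tissue interactions moved from 4594 to 2944 (bz1728), 481 to 190 (nbr6-t1) and 4072 to 2591 (taf12-t1). The overlap of nbr6-t1 and taf12-t1 moved to 202 in root (higher), and to 37 (higher) and 147 (lower) in shoot. That of the suppressor and nbr6-t1 moved to 265 in root (higher), and to 60 (higher) and 421 (lower) in shoot. The shoot reversal (lower) moved to 448.

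At the stricter threshold of 0.01 fewer genes pass by construction. The reversal gave 669 in root (lower), and 462 (higher) and 304 (lower) in shoot. The overlap of nbr6-t1 and taf12-t1 gave 120 and 379 in root and 26 and 111 in shoot, and that of the suppressor and nbr6-t1 gave 211 and 929 in root and 37 and 372 in shoot (higher, then lower). With an estimated correlation 16 of the 76 list calls of the pairwise comparisons held, and 104 were called with fry.

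Leaving out a library gave 118 (without shoot nbr6-t1 replicate 2) to 367 (without shoot nobiro6 replicate 3) genes for the shoot background interaction of 221, with 134 without shoot bz1728 replicate 2 and 128 without shoot nobiro6 replicate 1. The overlap of nbr6-t1 and taf12-t1 in root (higher, 336) ran from 209 (without root wt replicate 3) to 320, with 211 without root nbr6-t1 replicate 4. The shoot reversal (lower, 692) ran from 402 (without shoot bz1728 replicate 2) to 694, and the shoot overlap of suppressor and nbr6-t1 (higher, 120) from 79 (without shoot nbr6-t1 replicate 4) to 116. Of the counts with a library left out, 384 stayed within 1.5 times and 8 did not.

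Of 1224 values of named genes, 1181 kept their direction and call with DESeq2 and 1129 on log2(TPM + 1), where 20 and 59 lost the call and 23 and 36 gained it. Thinning, with fewer counts, kept 1098, lost 71 and gained 7, with the remaining values not tested at that depth. Leaving out a library kept 9708, lost 378 and gained 90. None of the named genes called changed direction under an alternative.

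Depth limits low genes: at the lowest depth 1 count is 0.375 CPM in root and 0.292 in shoot. Residuals of libraries with equal replicate numbers had a mean r of 0.014 in root (0 of 40 over 0.1) and -0.011 in shoot (6 of 40), and were the best match in 16 and 7 of 40 cases, where 10 are expected by chance. A weak pairing by number in root is therefore not excluded, and with the replicate block the counts stayed within 1.5 times. These residuals were compared within a tissue only. Pairing of the root and shoot libraries of a genotype was not checked, and the tissue interactions treat the libraries as independent.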

Other observations

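The 5 lists in this part were written after the results had been seen, around genes already known to change, so the numbers of called members are given without a test or an explanation.

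Sulfur deficiency genes in root were lower in 9 of 9 cases in nobiro6 against bz1728 (median -2.01), in 7 of 9 in nobiro6 against wt (-1.5), in 7 of 9 in nbr6-t1 (-0.92) and in 4 of 9 in taf12-t1 (-0.47). In bz1728 root 2 were higher and 5 lower. In shoot 0 of 8 were called in bz1728, and 3 were lower in nobiro6 against bz1728, 5 in nobiro6 against wt, 2 in nbr6-t1 and 1 in taf12-t1.

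Root triterpene genes were higher in 6 of 6 cases in bz1728 (median 1.64) and lower in 6 of 6 in nobiro6 against bz1728 (-1.06) and in 3 of 6 in taf12-t1 root (-0.64). Flavonoid pathway genes in root were higher in 5 of 5 cases in taf12-t1, and lower in 4 of 5 in bz1728, in nobiro6 against wt and in nbr6-t1. In shoot 7 of 11 were higher and 2 lower in taf12-t1. Clock genes in shoot were higher in 5 of 10 cases and lower in 1 in bz1728 against wt, lower in 7 in nobiro6 against bz1728, and lower in 1 in nobiro6 against wt. In taf12-t1 6 clock genes were higher and 2 lower in shoot, and 4 higher and 4 lower in root. The FLC family was higher in 3 of 5 cases in taf12-t1 shoot, and in 2 of 4 in root with 1 lower.

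BGAL9 stood at 62.6 ± 3.34 CPM in wt root, 49.4 ± 6.29 in bz1728, 0.345 ± 0.429 in nobiro6, 84.3 ± 7.58 in nbr6-t1 and 49.5 ± 8.75 in taf12-t1. In shoot the BGAL9 levels were 49.4 ± 3.23, 46.4 ± 3.49, 1.08 ± 0.39, 60.8 ± 1.33 and 42.7 ± 5.79 CPM in the same order. Only in nobiro6 was BGAL9 near 0, in both tissues. Whether this comes from the suppressor mutation or from another difference between the lines was not tested.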
